A study of Homo sapiens with 8 samples.

How the data were processed

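The measurements are counts of RNA-seq reads per gene in 8 libraries of SUM159, an established human triple-negative breast cancer cell line. Of these, 2 libraries came from ITGB4-high cells grown in dishes, 3 from clone 1 of ITGB4-low cells grown in dishes, and 3 from ITGB4-low clone 1 cells recovered from mouse lungs. Per the labels' protocols, the lung cells had been given by tail vein, the mice received bleomycin, a DNA-damaging drug that injures and inflames the lung, through the trachea, the lungs were dissociated, the suspension was cultured overnight, and cells carrying the red fluorescent protein tdTomato were sorted the next day. Polyadenylated RNA was captured with oligo dT beads and made into strand-marked (dUTP) libraries, per the labels' protocols.

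The deposited values are raw counts, whole numbers that had not been normalised, in 1 column per library, for 58336 Ensembl gene identifiers. The submitters' processing notes name STAR 2.7.1a and the genome build hg38. The counting program, its strand setting, the annotation release and any read filter are not given in the sources used here. Counts of genes that overlap, lie antisense to each other or share reads with a near-identical copy are therefore uncertain. Of the identifiers, 58216 matched GENCODE release 29, from which symbols, gene types and 1-based hg38 coordinates were taken, and 120 did not. A count of 0 in all libraries was found for 29279 genes. The library totals ran from 20.41 to 27.22 M counts, and mitochondrial genes took 1.16 to 1.74% of each library. No pair of libraries within a group was alike down to sampling noise (chi-square per degree of freedom 1.60 to 6.58), so none was treated as a copy of another. This does not show that they came from independent cultures or animals. Each was counted as 1 replicate, as labelled. The labels call the libraries biological replicates without saying from which cultures or animals they came, so p-values measure the spread between these samples.

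Groups and replicate numbers came from the sample titles. All 8 libraries entered 1 edgeR 4.0.16 fit in R 4.3.3 with a term per group, so that the 3 groups shared 1 estimate of the spread. Genes were kept by filterByExpr, which left 15220 genes with 99.93% of all counts and left out 13837 genes with at least 1 count. Library sizes were scaled with TMM factors, which ran from 0.975 to 1.012. The 3 pairwise differences were tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. Genes with an adjusted p under 0.05 are the ones called higher or lower. The standard error of a log2 fold change was the fold change divided by the square root of its F statistic. The biological coefficient of variation was 0.0452, with 5 residual degrees of freedom before moderation. Levels are CPM after TMM scaling, given as mean ± SD over libraries. Where a group had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the whole group. Where it had 1 to 3 counts, the ratio is given with an exact binomial 95% counting interval. Floors and intervals cover counting error only, since no molecular identifiers are recorded.

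Before the data were examined, 26 gene lists, the rule for named genes, the tests and the alternatives were fixed, apart from the additions named below. The lists were epithelial junction and keratin, basal epithelial and hemidesmosome, mesenchymal, EMT (epithelial-mesenchymal transition) transcription factors, EGF receptor family and ligands, ERK feedback and output, TGF-beta response, NF-kB and inflammatory cytokine, interferon-stimulated, MHC class I presentation, S phase, G2 and mitosis, dormancy-associated, p53 target, immediate-early and heat shock, unfolded protein response, hypoxia and glycolysis, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded, and markers of macrophages and myeloid cells, lymphocytes, endothelium, lung epithelium, lung fibroblasts and smooth muscle, and erythroid cells. The marker lists stand for lung cell types that a sort of tumour cells could hold, and mouse reads can be counted on a human gene only where the sequences are alike. Each list with at least 3 tested members was compared with all other genes by limma's camera (limma 3.58.1) on voom values, with a preset inter-gene correlation of 0.01, and adjusted over the 24 lists tested. Of the others, lymphocyte had 1 tested member and erythroid had 0. Camera was also run with a correlation estimated per list. Fry was run as well, which asks whether a set's genes move on balance one way and does not compare them with other genes.

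The named genes are 20 genes fixed in advance, the 10 called genes with the largest rise and the 10 with the largest fall per comparison among genes with at least 10 CPM in a group, non-overlapping libraries and a symbol that is not a clone identifier, up to 2 risen and 2 fallen members of each list by fold change (where none was called, the 2 with the smallest p), and, for genes called in both comparisons with ITGB4-low, the 5 with the largest smaller fold change among those higher in both, lower in both and opposite. Not every gene that the rule takes is printed. Genes named outside that rule were chosen after their values were seen, and are said to be so where they appear.

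Both comparisons with ITGB4-low use the same 3 libraries. Unchanged groups were therefore simulated 20 times against them, from the fitted means and dispersions, to give the overlap and covariance that shared controls produce with no effect. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter at 1 CPM and 50 counts, fits of the 2 compared groups alone, the replicate number as a block, leaving out each library in turn, an adjusted p under 0.01, and a test against a 2-fold change. The counts without part of chromosome 17 were added after the data were seen. The fits were tested on simulated counts in which known genes were changed 1.5-fold, 2-fold (67 genes each) or 4-fold (66 genes) in each comparison. Of genes changed 1.5-fold, 77.6% were recovered among 14913 genes for ITGB4-low against ITGB4-high, 74.6% among 14884 for lung-recovered against ITGB4-low, and 70.1% among 14912 for lung-recovered against ITGB4-high. At a 4-fold change the recovered shares were 95.5%, 98.5% and 97.0%, in the same order, and unchanged genes made up 3.11%, 7.25% and 7.43% of the calls. A simulated list raised 1.5-fold was called in all 3 comparisons by camera at either correlation and by fry, and 0 of 50 unchanged lists were called by any of them. The simulated genes varied independently of each other, so this does not test false calls of lists whose genes are correlated. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. No lung-recovered sample without bleomycin was analysed here.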

Results

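Gene expression was measured by poly(A) RNA sequencing in 8 libraries of SUM159, a human triple-negative breast cancer line whose cells carry many mesenchymal features. ITGB4-high cells (2 libraries, 27.22 and 25.92 M counts) and clone 1 of ITGB4-low cells (3 libraries, 20.41, 21.30 and 24.89 M) had been grown in dishes. The lung-recovered cells (3 libraries, 23.66, 21.03 and 26.30 M) were ITGB4-low clone 1 cells taken back from lungs of mice given bleomycin. The series title frames the study around inflammation, dormant cancer cells and the epithelial-mesenchymal state. Protein-coding genes took 98.0 to 98.1% of the counts in each library, and 15220 genes were tested. The first principal component of the log2 values (58.9% of the variance) set ITGB4-high apart from the 2 groups of clone 1 cells, and the next (26.3%) set the lung-recovered libraries apart from both dish-grown groups.

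ITGB4 (ENSG00000132470, hg38 chromosome 17, 75721328 to 75757818), an integrin beta subunit of the hemidesmosomes that anchor epithelial cells to the basement membrane, followed the labels in every dish-grown library. Its level was 419.9 and 376 CPM in the ITGB4-high libraries and 5.29, 7.46 and 9.13 CPM in the ITGB4-low libraries. In the lung-recovered libraries ITGB4 stood at 401, 375.5 and 407 CPM. The plot of basal and mesenchymal genes shows these levels per library.

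**Figure D1:**
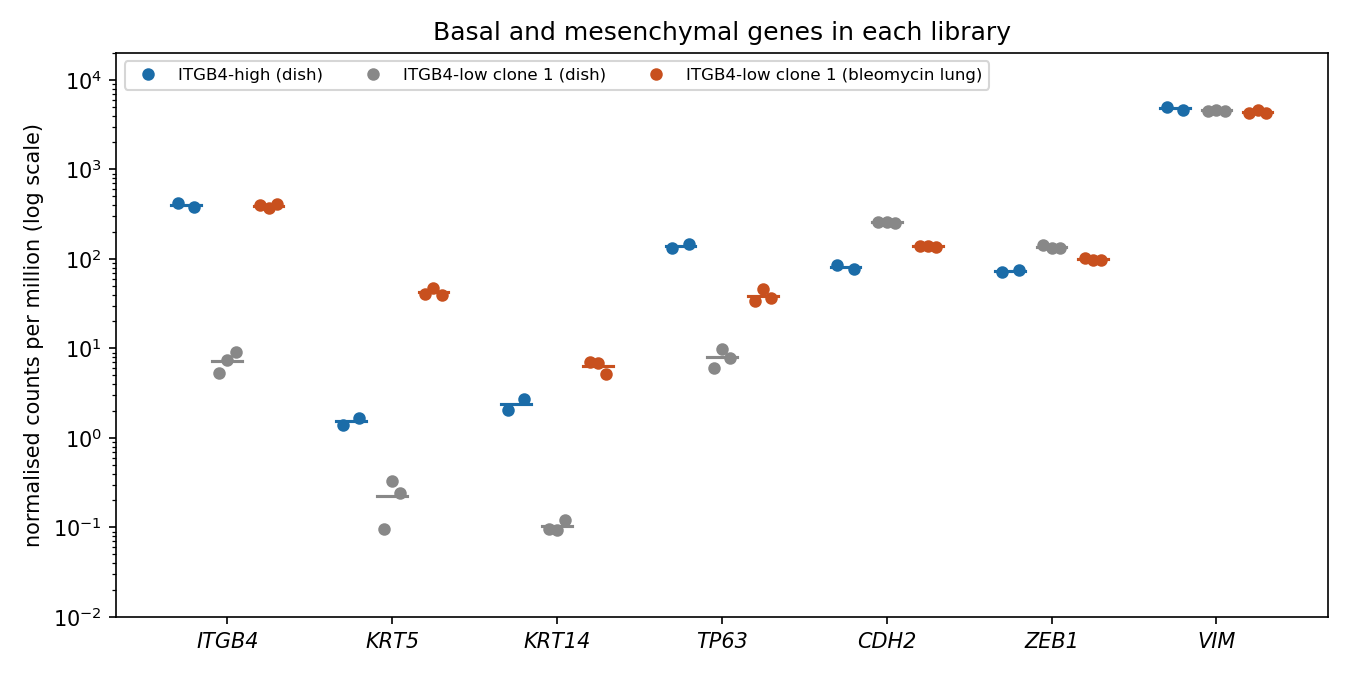
CPM (TMM-scaled, log axis) of 7 genes in each of the 8 libraries, with 1 point per library and a short line at each group mean. ITGB4 averaged 398 CPM in ITGB4-high, 7.29 CPM in ITGB4-low and 395 CPM in lung-recovered cells, while VIM stayed between 4378 and 4828 CPM in the group means.

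The first comparison set ITGB4-low clone 1 against ITGB4-high cells, both from dishes. All ITGB4-low libraries came from this clone, so traits of the clone and of the ITGB4-low state cannot be told apart here. ITGB4 fell from 398 ± 30.7 CPM (SD, n = 2) to 7.29 ± 1.93 CPM (n = 3), a log2 fold change of -5.75 (SE 0.10, edgeR adjusted p = 3.18e-19). Of 23 tested genes in the basal epithelial and hemidesmosome list, 13 fell, 4 rose and 6 were not called. The basal keratins KRT14 (ENSG00000186847, chromosome 17, 41582279 to 41586921; -4.44, SE 0.39) and KRT5 (ENSG00000186081, chromosome 12, 52514575 to 52520687; -2.74, SE 0.36) were lower as well, from levels of 2.38 and 1.54 CPM. CDH2 (ENSG00000170558, chromosome 18, 27950966 to 28177446), the mesenchymal cadherin, rose from 81.6 ± 6.17 to 256 ± 4.06 CPM (log2 fold change 1.65, SE 0.05). The EMT transcription factors ZEB1 (0.90, SE 0.05) and TWIST1 (1.33, SE 0.17) were higher.

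Of 15220 genes, 8554 differed between ITGB4-low and ITGB4-high, 4347 higher and 4207 lower in ITGB4-low. At 2-fold or more these were 1989 genes, of which 1388 were higher. Large rises among genes with at least 10 CPM in a group included those of the limb-patterning homeobox gene HOXD13 (a ratio of 320.0, 95% counting interval 88.3 to 2647, from 2 counts in ITGB4-high), ILDR2 (log2 fold change 7.14), the circadian transcription factor NPAS2 (6.29), the GDNF co-receptor GFRA1 (6.26), the procollagen peptidase ADAMTS2 (6.21), the adhesion molecule MCAM (5.60) and PCOLCE, an enhancer of procollagen processing (5.38). Genes that ITGB4-high cells expressed and ITGB4-low cells had all but lost included CYBA, a subunit of the NADPH oxidase (0 counts in ITGB4-low, at least 537.5-fold lower), the hyaluronan receptor LAYN (at least 333-fold lower) and B3GALNT1 (at least 316-fold lower), each from 0 counts in ITGB4-low. ALDH1A1, an aldehyde dehydrogenase used as a marker of stem-like breast cancer cells, was lower by a ratio of 2815 (779 to 23250). The Notch ligand JAG2 (ENSG00000184916, chromosome 14, 105140981 to 105168824) fell by 7.75 on the log2 scale, from 211 ± 17.4 to 0.967 ± 0.121 CPM. The granulocyte growth factor CSF3 was at 15.4 CPM in ITGB4-high and 0.0693 CPM in ITGB4-low. Libraries of the 2 groups did not overlap for 68.7% of genes, against 20% by chance.

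The mesenchymal list was higher in ITGB4-low: of 25 tested members 18 rose and 3 fell (18 and 4 adjusted over the list alone), with a median log2 fold change of 1.65 (camera adjusted p = 1.90e-07, adjusted p = 0.193 with an estimated correlation). The collagen gene COL6A3 rose from 69.1 ± 3.03 to 1192 ± 140.1 CPM, the matrix proteoglycan gene VCAN had a log2 fold change of 3.45. COL5A2 went the other way (-2.73). In the basal epithelial and hemidesmosome list, 13 of 23 members fell and 4 rose (13 and 4 adjusted over the list alone). Their median was -0.42 (camera adjusted p = 0.00169, adjusted p = 0.193 with an estimated correlation). KRT15, a basal keratin, was among the risen (3.17, SE 0.53, at 1.44 CPM). The epithelial junction and keratin list split evenly, with 5 of 15 members higher and 5 lower (5 and 5 adjusted over the list alone). The camera adjusted p was 0.625, and the median of -0.01 turned to 0.01 with upper-quartile scaling. Its members included the desmosomal plaque gene DSP (-1.81, SE 0.07), the polarity gene LLGL2 (-4.73, SE 0.37) and the tight-junction gene OCLN (1.48, SE 0.26). Of 12 EMT transcription factors 5 rose and 4 fell (5 and 6 adjusted over the list alone). Their median was -0.02 (0.0013 with upper-quartile scaling) and their mean -0.12, with camera's direction up (adjusted p = 0.520). SNAI1 was among those that fell (-1.40, SE 0.26). The log2 fold change of SNAI2 was -0.24 (adjusted p = 0.0150). This call ended without the second ITGB4-high library (-0.15, adjusted p = 0.217) or without ITGB4-low replicate 2 or replicate 3 (adjusted p = 0.0576 and 0.0651). VIM, the gene of the mesenchymal filament vimentin, was at 4561 ± 80.7 CPM in ITGB4-low and 4828 ± 278 in ITGB4-high (adjusted p = 0.181, and 0.0314 without the second ITGB4-high library). CDH1, the epithelial cadherin, had 0 counts in all 8 libraries. EPCAM and PRRX1 had at most 9 counts in any group and were not tested.

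Signalling lists moved as follows in ITGB4-low. Of 23 NF-kB and inflammatory cytokine genes 14 fell and 4 rose (the same numbers adjusted over the list alone). The list's median was -0.52 (camera adjusted p = 7.89e-04, adjusted p = 0.408 with an estimated correlation), with IL1B at -2.75 (SE 0.25) and the apoptosis inhibitor BIRC3 at 0.82 (SE 0.06). Of 20 genes of ERK feedback and output 12 fell and 2 rose (12 and 2 adjusted over the list alone). The median log2 fold change was -0.28 (camera adjusted p = 0.00562, adjusted p = 0.560 with an estimated correlation). The ERK phosphatases DUSP4 (-1.05) and DUSP6 (-0.90) fell. Of 12 EGF receptor family members and ligands 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.744). NRG1 (4.52, SE 0.15), AREG (1.54, SE 0.06) and EGFR itself (0.54, SE 0.06) rose and EPGN fell (-5.03, SE 0.22). EREG was 222 ± 24.7 against 218 ± 10.7 CPM (adjusted p = 0.774). The TGF-beta response list had 10 higher and 10 lower of 24 members (10 and 10 adjusted over the list alone, camera adjusted p = 0.943), with TGFB2 at 4.18 and the BMP-responsive ID1 at -1.63. Interferon-stimulated genes (11 higher and 4 lower of 29; 11 and 4 adjusted over the list alone, camera adjusted p = 0.520) and MHC class I presentation (6 higher and 7 lower of 18; 6 and 7 adjusted over the list alone, median 0.08, mean -0.03, camera direction down with adjusted p = 0.744) did not pass. HLA-B rose by 0.68 and the immunoproteasome subunit PSMB9 fell by 0.94 on the log2 scale.

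In the growth and stress lists, 30 of 51 genes of G2 and mitosis rose and 6 fell (33 and 6 adjusted over the list alone). The median of the list was 0.18 (camera adjusted p = 4.45e-04, adjusted p = 0.408 with an estimated correlation). The mitotic kinase AURKB was at 1.09 (SE 0.06). It lies at 0 to 10 Mb of chromosome 17, where genes had a median log2 fold change of 0.76. The fold of AURKB includes this shift of its region. In the S phase list 25 of 44 fell and 6 rose (26 and 6 adjusted over the list alone). The median was -0.23 (camera adjusted p = 5.99e-04, adjusted p = 0.340 with an estimated correlation). The uracil glycosylase gene UNG fell (-1.37) and the helicase subunit gene MCM6 rose (0.79). MKI67, the proliferation marker, was 400.0 ± 45.1 CPM in ITGB4-low and 371 ± 2.82 in ITGB4-high (adjusted p = 0.167, and 0.0351 without the second ITGB4-low library). Of 17 dormancy-associated genes 12 rose and 3 fell (13 and 3 adjusted over the list alone). The members' median was 0.80 (camera adjusted p = 0.00359, adjusted p = 0.193 with an estimated correlation). TGFB2 was among those that rose, the cell-cycle inhibitor gene CDKN1A fell (-1.02, SE 0.05). NR2F1, an orphan receptor tied to dormancy, was at 0.330 ± 0.0424 against 0.114 ± 0.106 CPM (adjusted p = 0.0555, but 0.0276 with limma-voom and 0.0267 without ITGB4-high replicate 1). In the p53 target list 17 of 27 fell and 3 rose (18 and 3 adjusted over the list alone). Their median log2 fold change was -0.23 (camera adjusted p = 0.00117, adjusted p = 0.193 with an estimated correlation), and ZMAT3 (-1.39) and GDF15 (-1.11) were among the fallen. Unfolded protein response genes were mostly higher (16 of 26, 7 lower, 17 and 7 adjusted over the list alone). The list had a median of 0.42 (camera adjusted p = 0.00189, adjusted p = 0.193 with an estimated correlation). So were hypoxia and glycolysis genes (21 of 32, 5 lower, 21 and 5 adjusted over the list alone). This list had a median of 0.36 (camera adjusted p = 0.00164, adjusted p = 0.379 with an estimated correlation). The chaperone gene PDIA4 (1.13) and the hypoxia targets CA9 (1.88) and BNIP3 (1.28) rose. Nuclear-encoded oxidative phosphorylation fell slightly (21 of 40 lower, 3 higher, 21 and 3 adjusted over the list alone, median -0.15, camera adjusted p = 0.00359, adjusted p = 0.408 with an estimated correlation). Cholesterol synthesis did not pass (9 of 24 higher, 4 lower, 9 and 4 adjusted over the list alone, camera adjusted p = 0.303). The immediate-early and heat shock (11 of 31 higher, 14 lower, 11 and 14 adjusted over the list alone, median -0.11, mean 0.03, camera adjusted p = 0.744) and mitochondrially encoded lists (3 of 13 higher, 0 lower, 3 and 0 adjusted over the list alone, camera adjusted p = 0.515) did not pass.

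The second comparison asked what changed in ITGB4-low clone 1 cells that had been in a bleomycin-treated lung. ITGB4 rose from 7.29 ± 1.93 to 395 ± 16.8 CPM (n = 3 and 3, log2 fold change 5.74, SE 0.10, edgeR adjusted p = 3.54e-19). The basal keratins KRT5 (7.52, SE 0.17) and KRT14 (5.85, SE 0.31) rose to 42.3 ± 4.04 and 6.37 ± 1.03 CPM. JAG2 (6.99, SE 0.10) rose to 124 ± 5.12 CPM. ITGA6, the alpha partner of ITGB4 in hemidesmosomes, rose by less (0.62, SE 0.04). The mesenchymal genes CDH2 (-0.89, SE 0.04) and ZEB1 (-0.47, SE 0.05) fell but stayed at 139 and 98.7 CPM. VIM was at 4378 ± 192 CPM (adjusted p = 0.362).

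In this comparison 4586 genes differed, 2238 higher and 2348 lower in the lung-recovered cells, and 839 at 2-fold or more (487 higher, 352 lower). Large rises outside the basal genes included those of the matrix proteoglycan gene BGN (a ratio of 419, 143 to 2033, from 3 counts in ITGB4-low), CSF3, the keratin KRT75 (6.92), the EGF receptor ligand EPGN (6.37), the interferon-induced XAF1 (6.19) and the cytokine-signalling factor STAT5A (5.48). Among genes with at least 10 CPM in a group, large falls included those of the ferroxidase gene HEPH (-3.69, SE 0.15), GFRA1 (-3.20), TMEM98 (-2.71), RNF150 (-2.28), the secretory-granule chaperone SCG5 (-2.21) and ILDR2 (-2.11). CD24, a surface glycoprotein, fell from 3.27 ± 0.167 to 0.323 ± 0.0191 CPM. Libraries did not overlap for 43.3% of genes, against 10% by chance.

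NF-kB and inflammatory cytokine genes rose almost as a whole: 21 of 23 members were higher and 0 lower (22 and 0 adjusted over the list alone), with a median log2 fold change of 1.34 (camera adjusted p = 7.65e-22, adjusted p = 0.154 with an estimated correlation). CSF3 reached 15.6 ± 1.35 CPM from 0.0693 ± 0.0828, and IL1B, a pro-inflammatory cytokine, had a log2 fold change of 3.47 (SE 0.22). Interferon-stimulated genes were higher in 14 of 29 cases and lower in 1 (14 and 1 adjusted over the list alone). Over the list, the median was 0.22 (camera adjusted p = 8.19e-05, adjusted p = 0.241 with an estimated correlation), with XAF1 and the antiviral OAS2 (3.56, SE 0.21) leading and the guanylate-binding protein GBP2 lower (-0.48). For MHC class I presentation 6 of 18 rose and 0 fell (the same numbers adjusted over the list alone). Their median was 0.04 (camera adjusted p = 0.0434, adjusted p = 0.417 with an estimated correlation). PSMB9 (0.77) and the peptide transporter TAP1 (0.45) rose. The list's call ended without the first ITGB4-low library (adjusted p = 0.178) or lung-recovered replicate 3 (adjusted p = 0.0594). ERK feedback and output genes were higher in 11 of 20 cases and lower in 0 (13 and 1 adjusted over the list alone). The list's median was 0.30 (camera adjusted p = 2.29e-06, adjusted p = 0.265 with an estimated correlation). Risen members included DUSP6 (1.27, SE 0.09) and EGR1 (1.33, SE 0.14). In the EGF receptor list 4 rose and 3 fell of 12 (5 and 3 adjusted over the list alone, camera adjusted p = 0.274). EREG (0.81, SE 0.06) and AREG (0.33, SE 0.05) rose while NRG1 (-1.89, SE 0.10) and EGFR (-0.38, SE 0.05) fell.

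The basal epithelial and hemidesmosome list rose (13 of 23 higher, 2 lower, 13 and 2 adjusted over the list alone, median 0.62, camera adjusted p = 2.89e-08, adjusted p = 0.133 with an estimated correlation). So did the epithelial junction and keratin list (7 of 15 higher, 2 lower, 7 and 3 adjusted over the list alone, median 0.27, camera adjusted p = 4.62e-04, adjusted p = 0.249 with an estimated correlation). DSP rose by 2.73 (SE 0.06) and LLGL2 by 3.06 (SE 0.44), while OCLN fell (-0.87, SE 0.21). The mesenchymal list did not pass and its members parted: 7 of 25 rose and 12 fell (7 and 12 adjusted over the list alone). Its median was -0.12 and its mean 0.26, with camera's direction down (adjusted p = 0.0837). It passed without ITGB4-low replicate 1 (adjusted p = 0.0386) or with no low-count filter (0.0268). The matricellular gene POSTN (5.20, SE 0.28) and the growth factor receptor gene PDGFRA (3.38, SE 0.10) rose, and the smooth-muscle protein gene TAGLN (-1.71) and the collagen cross-linker LOX (-1.16) fell. Of 12 EMT transcription factors 3 rose and 3 fell (4 and 4 adjusted over the list alone, median -0.0016, mean 0.29, camera direction up with adjusted p = 0.889), SNAI1 upward (1.89, SE 0.23). The TGF-beta response list had 9 higher and 9 lower of 24 (9 and 10 adjusted over the list alone, camera adjusted p = 0.644). Its members included TIMP3 at 1.60 and TGFB2 at -0.92.

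Genes of the cell cycle moved in opposite directions by phase and by small amounts. In the S phase list 21 of 44 rose and 0 fell (23 and 0 adjusted over the list alone). The median log2 fold change was 0.18 (camera adjusted p = 2.89e-08, adjusted p = 0.183 with an estimated correlation). Risen genes included CDCA7 (0.83) and the replication clamp PCNA (0.54). In the G2 and mitosis list 36 of 51 fell and 0 rose (37 and 0 adjusted over the list alone). The median of the list was -0.16 (camera adjusted p = 1.05e-09, adjusted p = 0.248 with an estimated correlation). Fallen genes included HMGB2 (-0.43) and MKI67 (-0.38, SE 0.06). Of 17 dormancy-associated genes 8 fell and 2 rose (11 and 3 adjusted over the list alone). The median was -0.37 (camera adjusted p = 0.00679, adjusted p = 0.182 with an estimated correlation). THBS1, a matrix glycoprotein, fell from 885 ± 52.2 to 325 ± 34.2 CPM and IGFBP5 by 2.07 on the log2 scale, while the stress-responsive repressor BHLHE40 (0.66) and CDKN1A (0.44) rose. NR2F1 was at 0.634 ± 0.116 against 0.330 ± 0.0424 CPM (adjusted p = 0.0859). In the p53 target list 11 of 27 rose and 4 fell (11 and 4 adjusted over the list alone). The members' median was 0.09 (camera adjusted p = 0.0203, adjusted p = 0.249 with an estimated correlation), with GDF15 at 1.13 (SE 0.07) and the mitochondrial-quality gene SPATA18 at 2.27 (SE 0.30). Nuclear-encoded oxidative phosphorylation was higher in 17 of 40 and lower in 0 (18 and 0 adjusted over the list alone). Their median log2 fold change was 0.12 (camera adjusted p = 2.28e-05, adjusted p = 0.249 with an estimated correlation). Of the mitochondrially encoded genes 0 of 13 passed edgeR's threshold (0 also adjusted over the list alone, camera adjusted p = 0.644). In the immediate-early and heat shock list 10 of 31 rose and 7 fell (10 and 7 adjusted over the list alone, camera adjusted p = 0.403). Cholesterol synthesis did not pass (2 of 24 higher, 5 lower, 2 and 5 adjusted over the list alone, camera adjusted p = 0.603). Nor did the unfolded protein response (3 of 26 higher, 9 lower, 3 and 10 adjusted over the list alone, camera adjusted p = 0.0809), though it did without ITGB4-low replicate 1 (adjusted p = 0.0335) or with no low-count filter (0.00688). Hypoxia and glycolysis did not pass either (3 of 32 higher, 11 lower, 4 and 11 adjusted over the list alone, camera adjusted p = 0.0610). It passed without ITGB4-low replicate 1 (adjusted p = 0.0335) or replicate 3 (0.0459), without lung-recovered replicate 2 (0.0196) or with no low-count filter (0.00780).

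Markers of other cells that a lung suspension can hold differed in level in the sorted cells. The macrophage genes C1QA and TYROBP and the haemoglobin gene HBB, named with SFTPC and PECAM1 after their values were seen, had 0 counts in the lung-recovered libraries. C1QA, TYROBP and HBB were at 0 CPM in ITGB4-low as well. The surfactant gene SFTPC was at 0.0125 CPM (0 in ITGB4-low) and the endothelial PECAM1 at 0.373 CPM (0.139 in ITGB4-low). The macrophage gene MARCO rose from 0.788 to 1.46 CPM, a call that ended with DESeq2 (adjusted p = 0.0677). Of the marker lists, the dish-grown ITGB4-low cells themselves expressed at 1 CPM or more 2 of 25 macrophage and myeloid genes, 1 of 18 lymphocyte, 5 of 18 endothelial, 4 of 20 lung epithelial, 9 of 20 fibroblast and smooth muscle and 0 of 10 erythroid genes. In the lung-recovered cells these numbers were 3, 1, 5, 4, 9 and 0. Against ITGB4-low, 2 macrophage and myeloid genes rose and 1 fell of 7 tested (2 and 1 adjusted over the list alone, camera adjusted p = 0.603). Among endothelial genes 2 rose and 3 fell of 8 (2 and 3 adjusted over the list alone, median -0.47, mean 0.35, camera direction down with adjusted p = 0.651). Among lung epithelial genes 2 rose and 2 fell of 6 (3 and 2 adjusted over the list alone, median 0.09, mean -0.31, camera direction up with adjusted p = 0.651). Of 10 fibroblast and smooth muscle genes 2 rose and 6 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0683). That list passed without ITGB4-low replicate 1 (adjusted p = 0.0386) or replicate 3 (0.0459) or with no low-count filter (0.0305). Some listed genes were expressed in all groups, such as PDPN, at 290 ± 6.61 CPM in lung-recovered and 227 ± 15.7 CPM in ITGB4-low cells, and PDGFRA reached 36.5 ± 0.908 CPM from 3.50 ± 0.181. The endothelial SOX18 went from 0 to 47 counts (at least 14.6-fold) and the cathepsin gene CTSS from 18 to 68 counts. LAPTM5, a lysosomal gene of blood cells, fell from 101 ± 12.3 to 50.2 ± 1.76 CPM, and the lymphocyte-list gene IL7R rose from 2.27 ± 0.564 to 11.5 ± 1.46 CPM. Between the dish-grown groups, the fibroblast and smooth muscle list was higher in ITGB4-low (7 of 10 higher, 2 lower, 7 and 2 adjusted over the list alone, median 2.12, camera adjusted p = 0.00395, adjusted p = 0.193 with an estimated correlation), with MCAM and the collagen gene COL13A1 (5.05, SE 0.29) among the risen members. The macrophage (camera adjusted p = 0.873), endothelial (0.195) and lung epithelial (0.477) lists did not pass there.

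The lung-recovered cells differ from the dish-grown cells in passage through the lung, bleomycin, dissociation, overnight culture and sorting together. No list kept its call in camera with an estimated correlation in any of the 3 comparisons, and in mixed splits of the 6 ITGB4-low and lung-recovered libraries the test with the preset correlation still called 2 to 8 lists. Each mixed split held unequal numbers of the groups on its sides, so part of the real difference remained and may account for these calls.

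**Figure D2:**
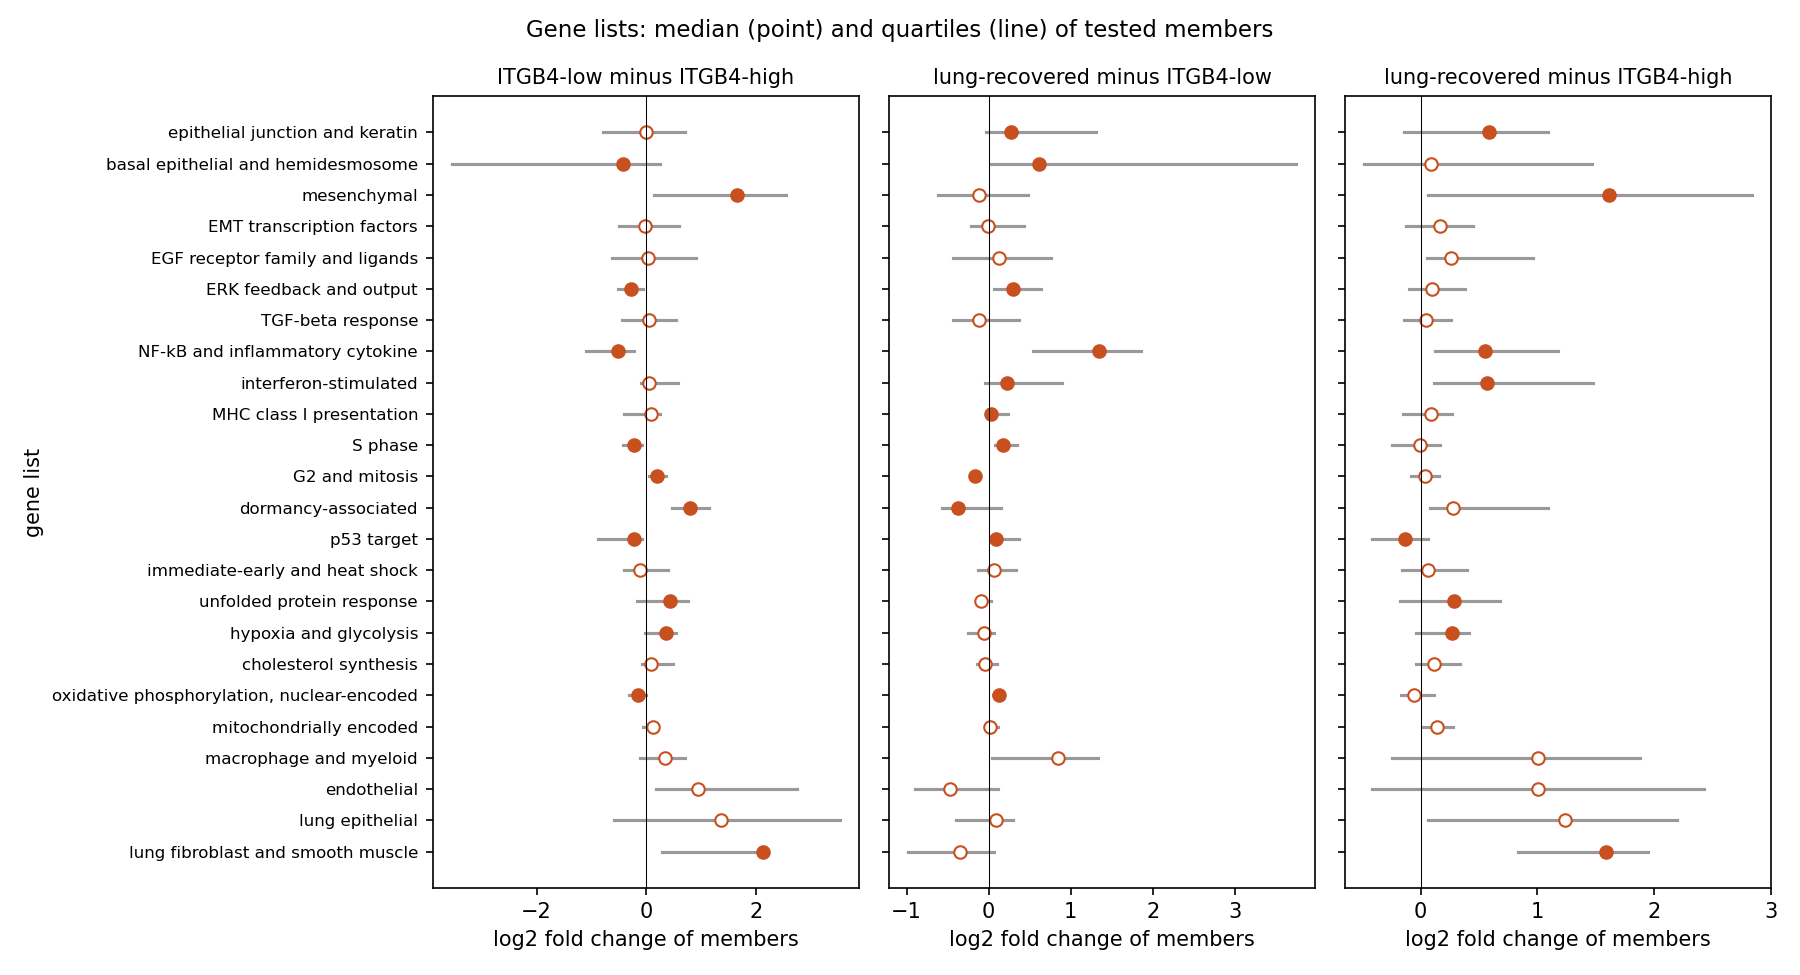
Median (point) and quartiles (line) of the log2 fold changes of each list's tested members in the 3 comparisons; filled points passed camera's adjusted threshold with the preset correlation, and none passed with an estimated correlation. The NF-kB and inflammatory cytokine medians were -0.52, 1.34 and 0.55 from left to right, and the mesenchymal medians 1.65, -0.12 and 1.61.

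The comparison with ITGB4-high cells asked how close the lung-recovered cells came to the ITGB4-high cells. ITGB4 stood at 395 ± 16.8 against 398 ± 30.7 CPM (log2 fold change -0.01, SE 0.07, edgeR adjusted p = 0.903, n = 3 and 2). KRT5 and KRT14 went above the ITGB4-high level (4.78, SE 0.14, and 1.41, SE 0.19), while TP63, the master regulator of basal epithelium, and its target S100A2 stayed below it (-1.87, SE 0.10, and -1.39, SE 0.07). Several mesenchymal genes stayed above ITGB4-high: CDH2 by 0.76 (SE 0.05), ZEB1 by 0.44 (SE 0.05), TWIST1 by 0.94 (SE 0.17) and COL6A3 by 5.02 (SE 0.09), at 2242 ± 67.2 CPM. Others were lower than in ITGB4-high: COL5A2 (-2.49, SE 0.10) and VIM (-0.14, SE 0.05, adjusted p = 0.0257). The VIM call ended without ITGB4-high replicate 1 (adjusted p = 0.209) or lung-recovered replicate 1 (0.125) or replicate 3 (0.116). ALDH1A1 and LAYN did not return, with a ratio of 3016 (835 to 24914) and at least 357-fold lower levels than in ITGB4-high.

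Between lung-recovered and ITGB4-high cells 7789 genes differed, 3990 higher and 3799 lower, and 1611 at 2-fold or more (1230 higher). Large rises included those of the matricellular gene THBS2, at 104 ± 1.35 CPM from 2 counts in ITGB4-high (a ratio of 2719, 753 to 22458), XAF1 (from 1 count, a ratio of 768, 137 to 30357), ITGBL1 (7.83, SE 0.16), the insulin-like growth factor carrier IGFBP3 (6.09, SE 0.28) and the gap-junction gene GJB2 (5.88, SE 0.23). NUP210 (-5.24), HTATIP2 (-6.07), KDELC2 (-5.96) and RASIP1 (-5.08) were among the large falls. Libraries did not overlap for 66.8% of genes, against 20% by chance. The mesenchymal list was higher (18 of 25 members, 5 lower, the same numbers adjusted over the list alone). It had a median of 1.61 (camera adjusted p = 2.15e-08, adjusted p = 0.259 with an estimated correlation). NF-kB and inflammatory cytokine genes were higher too (16 of 23, 1 lower, the same numbers adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.09e-04, adjusted p = 0.391 with an estimated correlation). The chemokine CCL20 (2.67, SE 0.22) was higher and the NF-kB inhibitor NFKBIA slightly lower (-0.20, SE 0.05). Of 29 interferon-stimulated genes 18 rose and 2 fell (the same numbers adjusted over the list alone), with a median of 0.57 (camera adjusted p = 9.97e-04, adjusted p = 0.343 with an estimated correlation). Fibroblast and smooth muscle genes were higher in 7 of 10 cases and lower in 2 (the same numbers adjusted over the list alone), with a median of 1.59 (camera adjusted p = 9.80e-04, adjusted p = 0.341 with an estimated correlation). MCAM (5.26, SE 0.08) was among them. The other tested marker lists did not pass here. Macrophage and myeloid genes had 4 higher and 2 lower of 7 (median 1.00, camera adjusted p = 0.559). Endothelial genes had 4 higher and 2 lower of 8 (median 1.01, camera adjusted p = 0.264). Lung epithelial genes had 3 higher and 1 lower of 6 (median 1.24, camera adjusted p = 0.264).

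Epithelial junction and keratin genes rose in 8 of 15 cases and fell in 2 (the same numbers adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.0232, adjusted p = 0.391 with an estimated correlation). The tight-junction gene CLDN1 was at 195 ± 7.76 against 54.8 ± 1.07 CPM. In the unfolded protein response list 14 of 26 rose and 8 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.0232, adjusted p = 0.343 with an estimated correlation). In hypoxia and glycolysis 18 of 32 rose and 5 fell (the same numbers adjusted over the list alone, camera adjusted p = 0.0191, adjusted p = 0.391 with an estimated correlation). Of 27 p53 targets 11 fell and 5 rose (the same numbers adjusted over the list alone, camera adjusted p = 0.0337, adjusted p = 0.343 with an estimated correlation). The p53 call ended without the second ITGB4-high library (adjusted p = 0.0511) or the first lung-recovered library (adjusted p = 0.0608). The basal list did not pass, with 9 of 23 higher and 8 lower (9 and 8 adjusted over the list alone). Its median was 0.09 and its mean 0.74, with camera's direction down (adjusted p = 0.976). Growth lists did not pass. In the S phase list 10 rose and 16 fell of 44 (11 and 16 adjusted over the list alone, camera adjusted p = 0.442), and its median of -0.0072 turned to 0.0040 with upper-quartile scaling. In G2 and mitosis 13 rose and 11 fell of 51 (13 and 11 adjusted over the list alone, camera adjusted p = 0.559), with MKI67 at -0.27 (SE 0.06). The mitochondrially encoded list (5 of 13 higher, 0 lower, 3 and 0 adjusted over the list alone) had an adjusted p of 0.274 in camera and passed without ITGB4-high replicate 1 (0.0201). The EGF receptor list (6 of 12 higher, 1 lower, the same numbers adjusted over the list alone) had 0.0905 and passed with no low-count filter (0.0282). Dormancy-associated genes had 8 higher and 2 lower of 17 (8 and 2 adjusted over the list alone, camera adjusted p = 0.133), with NR2F1 higher (2.43, SE 0.56) and CDKN1A lower (-0.58, SE 0.05).

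The last question was whether the lung-recovered cells had moved toward the ITGB4-high cells. Measured against the same ITGB4-low libraries, 3438 genes were called in both the ITGB4-high and the lung-recovered comparison. Of these, 2880 (83.8%) moved in the same direction, 1292 higher and 1588 lower than in ITGB4-low, and 558 in opposite directions. Independent lists of these sizes would share 619 higher and 671 lower genes and 1288 with opposite signs. Unchanged groups simulated 20 times against these libraries shared 0 calls under edgeR. These groups held no difference at all, so hardly any call could be shared, and the overlap of changed groups was not simulated. The covariance of the log2 fold changes across genes was 0.308 against 0.0211 to 0.0282 in the simulations, a difference of 0.283 from their mean. The correlation of the fold changes was 0.428, within the simulated range of 0.416 to 0.518 (mean 0.476). In the simulations this correlation came from noise in the shared libraries alone, however small that noise was. It therefore cannot show whether groups with real differences were more alike than shared libraries make them. Over all tested genes, called or not, 66.2% had the same sign in both comparisons, against a mean of 65.3% (64.5 to 66.1%) in the simulations. The same limit holds for this share. The 3 ITGB4-low libraries could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared libraries.

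Genes higher in both than in ITGB4-low included CSF3, JAG2, the laminin receptor BCAM (8.28 ± 0.465 CPM in lung-recovered and 3.98 ± 0.179 in ITGB4-high, from 2 counts in ITGB4-low) and LAMC3, a laminin chain at 0 counts in ITGB4-low. Lower in both were the calcium channel gene CACNA1C, the immune receptor gene SLAMF7, HEPH, TENM4 and the lung and thyroid transcription factor NKX2-1, which ITGB4-low cells expressed at 1.04 ± 0.118 CPM. THBS2, ITGBL1 and GJB2 went in opposite directions: they were lowest in ITGB4-high (THBS2 at 0.0377 CPM) and highest in the lung-recovered cells (104 CPM). Of the 8554 genes that differed between ITGB4-low and ITGB4-high, 2880 (33.7%) moved toward ITGB4-high in the lung-recovered cells, 558 (6.52%) moved away and 5116 were not called. Among the 2880, 1416 still differed from ITGB4-high on the same side, 195 had passed beyond it and 1269 were not called against it. The mean absolute log2 difference over all genes was 0.526 between ITGB4-low and ITGB4-high, 0.293 between lung-recovered and ITGB4-low and 0.465 between lung-recovered and ITGB4-high.

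**Figure D3:**
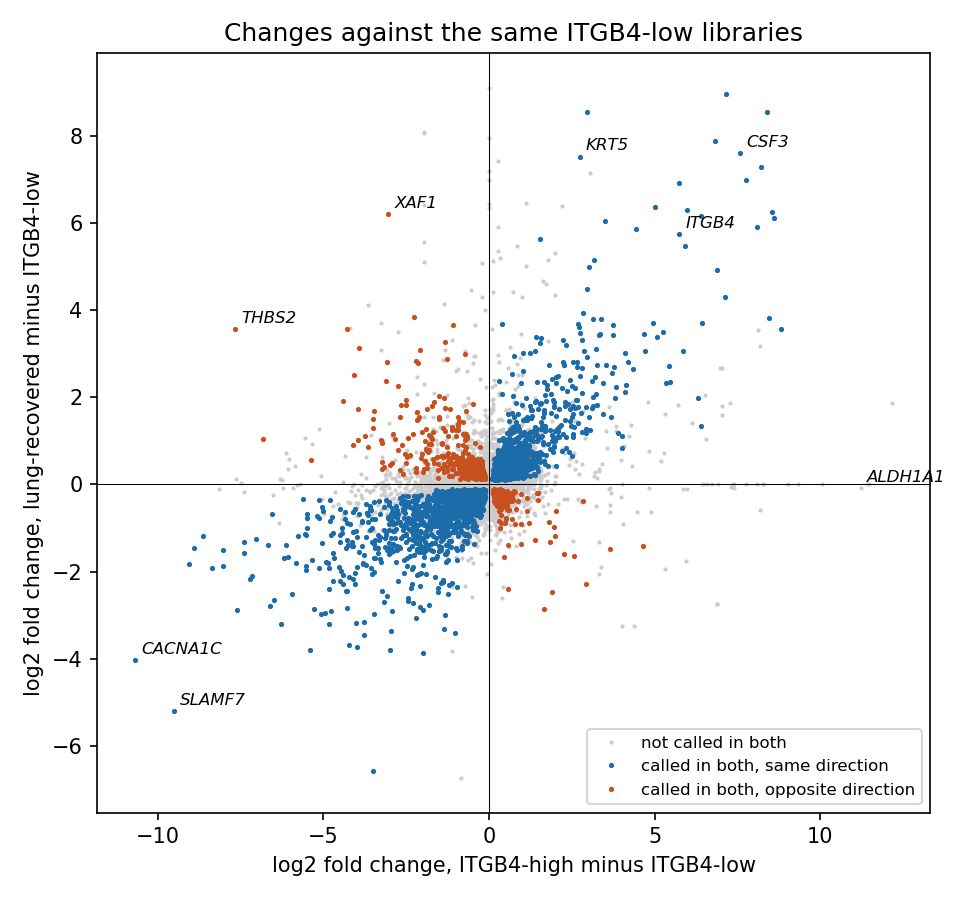
Log2 fold change of the lung-recovered cells (vertical axis) and of the ITGB4-high cells (horizontal axis) against the same ITGB4-low libraries, with 1 point per tested gene; blue points are the 2880 genes called in both in the same direction and orange points the 558 called in opposite directions. Fitted fold changes of genes with almost no counts in a group, such as ALDH1A1, depend on the prior count, and both axes share the ITGB4-low libraries, which tilts the cloud even with no effect.

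**Figure D4:**
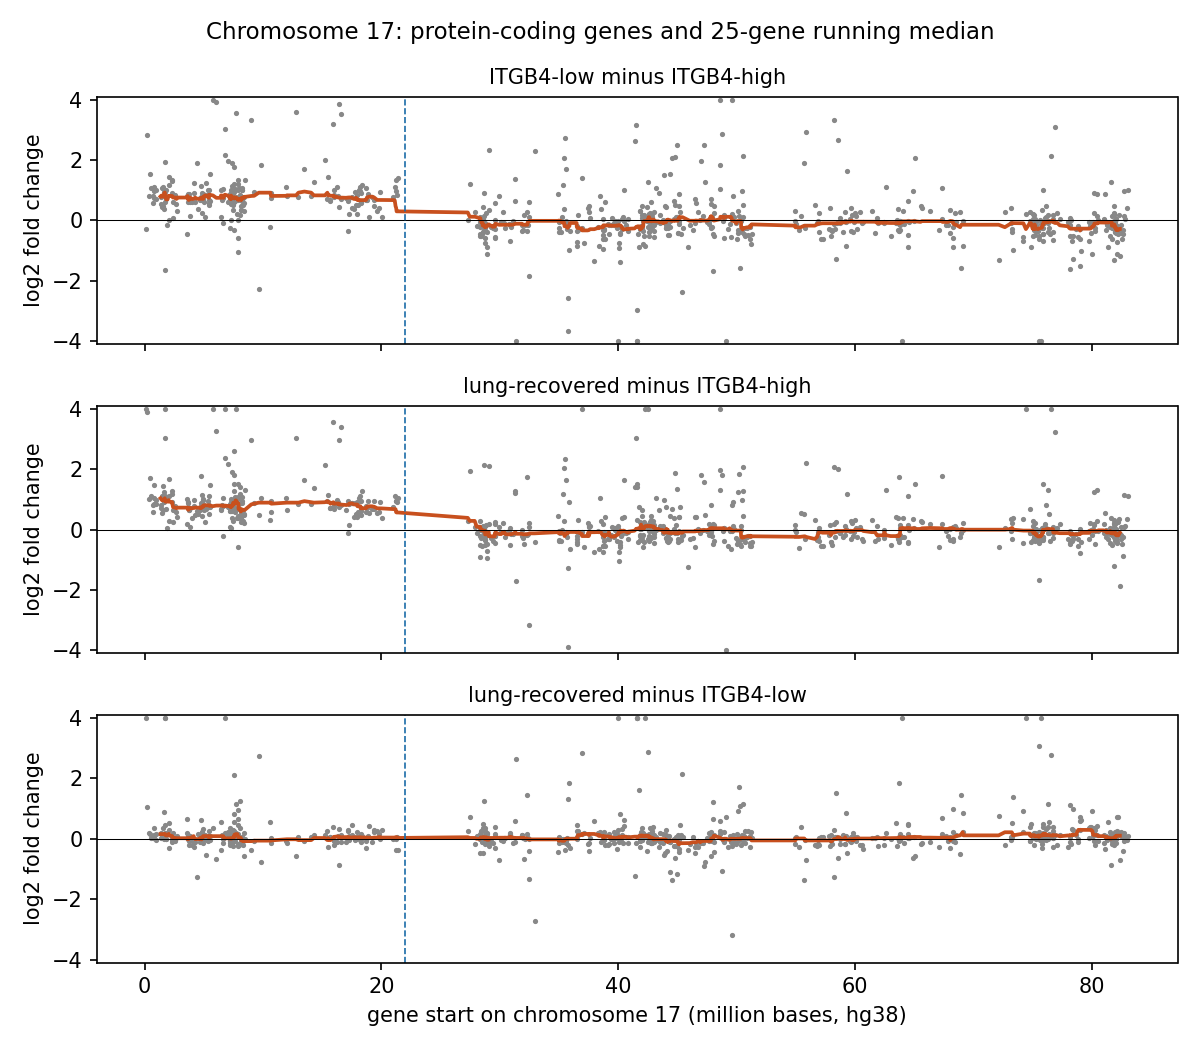
Running median over 25 genes of the log2 fold changes of protein-coding genes along chromosome 17 (start in Mb, hg38; log2 units) in the 3 comparisons, with 1 grey point per gene, points beyond 4 or -4 drawn at those values, and a dashed line at 22 Mb. The 215 genes before the line had medians of 0.77 for ITGB4-low against ITGB4-high, 0.04 for lung-recovered against ITGB4-low and 0.82 for lung-recovered against ITGB4-high.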

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

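The counts without the first 22 Mb of chromosome 17 were added after the data were seen; the other alternatives were fixed before. No call of a named gene or list turned its direction under the alternatives run. The medians of 3 lists near 0, none of them called, changed sign with upper-quartile scaling. Which direction held more calls turned under some alternatives in each comparison. For ITGB4-low against ITGB4-high it turned without either ITGB4-high library (3650 higher and 3750 lower without replicate 1), without ITGB4-low replicate 2 and without the start of chromosome 17 (4140 and 4193). For lung-recovered against ITGB4-low it turned with DESeq2, with no low-count filter, in the test against a 2-fold change (245 and 115), without ITGB4-high replicate 1 (2394 and 2354) and in the fit of the 2 groups alone. For lung-recovered against ITGB4-high it turned without ITGB4-low replicate 2 (3836 and 3864) and without the start of chromosome 17 (3772 and 3781). Of 369 gene results 334 kept their side of the threshold in all their alternatives, as did 22 of 72 list results. The test against a 2-fold change left 1137, 360 and 895 genes for ITGB4-low against ITGB4-high, lung-recovered against ITGB4-low and lung-recovered against ITGB4-high, fewer by its construction, and asking for 2 fold or more in both comparisons with ITGB4-low left 485 genes called in the same direction, 87.7% of those called in both. With an estimated correlation camera called 0 lists in each comparison (6, 4 and 2 at an unadjusted p under 0.05). Fry, which asks another question, called 19 and 14 lists for the comparisons of ITGB4-low and lung-recovered cells with ITGB4-high. For the lost lists the cause was not tested. The dormancy-associated list lost its call though its estimates were below the preset 0.01. They were -0.0030 for ITGB4-low against ITGB4-high and -7.15e-04 for lung-recovered against ITGB4-low. A higher correlation was thus not the cause for that list, while the other called lists had estimates above 0.01. DESeq2 called 7743, 3932 and 7040 genes, and without the start of chromosome 17 the comparisons with ITGB4-high kept 8333 and 7553. Leaving out each library in turn gave 7400 to 8542, 3532 to 4748 and 6623 to 8145 genes, at 2-fold or more 1907 to 1992, 769 to 875 and 1558 to 1623, genes called in both in the same direction 2277 to 2776 (2880 with all libraries), and lists 12 to 12, 10 to 14 and 7 to 9; a lone ITGB4-high library was assumed to vary like the other groups. With the replicate number as a block 7990, 4146 and 7213 genes were called, 2551 called in both in the same direction, and 12, 11 and 8 lists. Under the block SNAI2 between ITGB4-low and ITGB4-high had an adjusted p of 0.0528, and VIM between lung-recovered and ITGB4-high cells 0.0952. Whether the numbers pair the samples cannot be settled with so few libraries. Same-numbered lung-recovered and ITGB4-low libraries correlated at 0.0052, 0.0400 and 0.0134, and differently numbered ones at -0.0305 to 0.0207. ITGB4-low replicates 1 and 2 correlated best with their own number. ITGB4-low replicate 3 correlated best with lung-recovered replicate 1 (0.0207). At 20.41 M counts, genes near 0 counts in a group have folds set by counting error.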

Other observations

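The tests here were chosen after their results were seen, except that of GC content and gene length. Gene families taken by the stem of the symbol (213 stems with at least 8 tested genes) showed further shifts, none of which held with an estimated correlation, and the members named here were chosen after their values were seen. Ribosomal protein genes were lower in ITGB4-low than in ITGB4-high: of 47 genes with the stem RPL 43 fell and 2 rose, with a median log2 fold change of -0.52 (camera adjusted p = 4.48e-15, adjusted p = 0.831 with an estimated correlation), for example RPL24 (-1.10, SE 0.06) and RPL17 (-1.01, SE 0.06). In the lung-recovered cells 17 of them rose against ITGB4-low and 0 fell (median 0.12, camera adjusted p = 2.91e-04, adjusted p = 0.922 with an estimated correlation), with RPL7A at 0.23, and against ITGB4-high 42 stayed lower (median -0.40). Reads of these genes can be shared with their many processed copies, so the levels of single members are uncertain.

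The GALNT family, enzymes that start O-linked glycosylation of mucin-type proteins, was higher in ITGB4-low (7 of 9 rose and 1 fell, median 0.48, camera adjusted p = 0.0380, adjusted p = 0.831 with an estimated correlation) and lower again in the lung-recovered cells (6 fell and 1 rose, median -0.33, camera adjusted p = 0.00483, adjusted p = 0.922 with an estimated correlation). GALNT15 moved by 2.78 and -1.50 and GALNT5 by 1.70 and -0.84 on the log2 scale. Against ITGB4-low, lung-recovered cells had more RNA of the TRAF stem, adaptors of TNF receptor signalling (7 of 9 rose, 0 fell, median 0.25, camera adjusted p = 0.00368, adjusted p = 0.922 with an estimated correlation): TRAF1 (0.64, SE 0.12), TRAF3 (0.53, SE 0.04) and the associated gene TRAF3IP2 (0.24, SE 0.05) were among them. The MCM stem, mostly subunits of the replication helicase and partly members of the S phase list, rose as well (6 of 10, 0 fell, median 0.25, camera adjusted p = 0.0115, adjusted p = 0.922 with an estimated correlation), with MCM5 at 0.45 and MCM4 at 0.35.

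ITGB4, KRT5 and JAG2 stood in the lung-recovered cells far above ITGB4-low. Carry-over of ITGB4-high cells would need nearly all cells to be such cells, since ITGB4 reached their level, and would bring the first 22 Mb of chromosome 17 back down by 0.77 on the log2 scale. The region's median against ITGB4-low was 0.0401 (bootstrap interval 0.02 to 0.07), which argues against it. Growth of a minority already in the ITGB4-low culture and a change of state within the cells cannot be told apart: among the 133 genes that rose at least 2-fold to 10 CPM or more, BGN had the lowest ITGB4-low level, 0.241% of that in the lung-recovered cells, and 0 genes had no counts in ITGB4-low, so a share below that value may have been present. RNA of single cells was not measured.

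Genes in the first 22 Mb of chromosome 17 were higher in ITGB4-low than in ITGB4-high as a block: of 215 protein-coding genes 184 were higher and 3 lower, with a median log2 fold change of 0.77 (0.72 to 0.82), against -0.10 in the rest of the chromosome and -0.01 on other chromosomes. After GC content and gene length were fitted over the other genes, the residual median was 0.69 (0.65 to 0.74), so these trends were not the whole cause. The lung-recovered cells, which come from the ITGB4-low clone, had a median of 0.82 (0.77 to 0.88) against ITGB4-high, with 194 genes higher and 0 lower by edgeR, and per library the medians over the 195 of these genes with a mean of at least 1 CPM were 0.74, 0.76 and 0.75 in ITGB4-low and 0.80, 0.79 and 0.82 in lung-recovered cells. A difference between the clone and the ITGB4-high cells that passage through the lung kept would leave such a median in the lung-recovered cells. Whether the cells differ in copies of the region, and in which of them these changed, was not tested, since DNA was not measured. Of 231 bins of 10 Mb, 25 had a median beyond 0.3 between ITGB4-low and ITGB4-high and 0 between lung-recovered and ITGB4-low cells, where the largest was 0.212. Outside chromosome 17, the largest between ITGB4-low and ITGB4-high was -0.67, at 40 to 50 Mb of chromosome 18. The chromosome 3 bins at 170 to 180 Mb, which holds ZMAT3, and 180 to 190 Mb, which holds TP63, each had a median of -0.36. Folds of single genes in such bins include the shift of their region.

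NF-kB and inflammatory cytokine genes rose in the lung-recovered cells by a median log2 fold change of 1.34. RNA of mouse immune or other lung cells would bring the markers of those cells along. The 86 markers with a mean under 0.5 CPM in ITGB4-low went from 4.69 ± 0.799 to 6.73 ± 0.175 CPM in sum. This gain was 0.0947% of the 2150 CPM by which the NF-kB list rose. For the cells that these markers stand for, it argues against such RNA as the source of the summed gain. Abundant members such as BIRC3 (512.8 to 793.5 CPM) weigh most in that sum. The test does not decide for members at low levels, such as IL1B (0.496 to 5.67 CPM) and CCL20 (0.666 to 5.17 CPM). Markers at a higher level in ITGB4-low were left out of the sum. Among those, PDGFRA (3.505 to 36.47 CPM) and IL7R (2.267 to 11.53 CPM) rose, and others fell, such as LAPTM5 (101.1 to 50.21 CPM). Mouse reads are counted on a human gene only where the sequences are alike, so these markers can miss mouse RNA. Dissociation, overnight culture and sorting cannot be told apart from the stay in the lung and bleomycin, because no dish-grown sample went through these steps: the immediate-early and heat shock list had a median of 0.0695 (-0.01 to 0.20), which leaves an earlier response to handling possible.

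The 6 ITGB4-low and lung-recovered libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. In 1 of the 10, the real split, edgeR called 4669 genes (5984 at an unadjusted p under 0.05). The highest of the others was 0 genes (at most 482 at an unadjusted p under 0.05; 0 by limma-voom and 2 by DESeq2). For lists the real split gave 11 and the highest other 8, again 1 of 10 with as many. The other splits mixed the groups in unequal numbers, so they still held part of the real difference. Mixing also widens the spread within each side, which by itself keeps gene calls few. These splits therefore do not show what libraries without a difference would give.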
